A study of Homo sapiens with 8 samples.

How the data were processed

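RNA from KG1A and U937 cells was sequenced in 8 libraries: 2 of KG1A in PBS, 2 of KG1A in 10 mM dG, 2 of U937 in PBS and 2 of U937 in 10 mM dG. Cell line, treatment and replicate number were taken from the sample titles. Per the labels' protocols, cells grew in RPMI medium with dialyzed serum, total RNA was column-purified, and libraries were made with a Kapa mRNA kit. A kit of this kind selects RNA with a poly(A) tail, so RNAs without a tail are measured only as carryover.

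The deposited count table gives whole-number read counts for 57992 genes, with gene identifiers, coordinates and exon lengths. The tools bcl2fastq 2.18.0.12, TopHat2 and HTSeq 0.11.2 and the build hg38 (GRCh38) are named in the submitters' processing notes, without their roles or settings. The annotation release, the strand setting and the treatment of reads that match several genes were not given in the sources used here. Reads of near-identical genes (such as HSPA1A and HSPA1B, or members of the HLA and histone clusters) and of overlapping or antisense genes may therefore be divided arbitrarily, and values of such genes are uncertain. The deposited RPKM table was recomputed from the counts: the authors' RPKM equalled reads per kilobase of exon length and per scaled library size, with 1 factor per library, and those factors matched edgeR's TMM factors over all genes. Of the gene identifiers, 57388 matched GENCODE 29, which supplied gene types.

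Library totals ran from 21053724 to 31135338 counts. CPM are edgeR's counts per scaled library size (TMM), and 1 count equalled 0.0321 to 0.0475 CPM before that scaling. Counting intervals at 95% and the floor of 3 counts per group, used where a group held no reads, cover counting error only, since the reads carry no molecular identifiers.

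Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided) under R 4.3.3, on the counts as deposited, after filterByExpr left 18314 genes and with TMM size factors. All 8 libraries entered 1 model with a mean for each combination of line and treatment, which left 4 residual degrees of freedom per gene. The common biological coefficient of variation was 2.51%, with 31.0 prior degrees of freedom. The contrasts were dG against PBS in KG1A, dG against PBS in U937, the difference between these effects (the U937 effect minus the KG1A effect), and U937 against KG1A in PBS. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05 and no minimum fold change. Every gene-level adjusted p given here comes from this test, and every ± after a log2 fold change is its standard error.

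The design, the 32 gene lists (754 entries, of which 1 symbol matched no gene), the rule for named genes and the alternatives were fixed before the data were examined. The lists covered dNTP synthesis and salvage, purine synthesis and salvage, monocyte and macrophage markers, late neutrophil markers, primary granule genes, phagocyte oxidase, MHC class II presentation, stem and progenitor genes, myeloid transcription factors, DNA replication, G1/S cyclins and E2F, G2/M and mitosis, replication-dependent histones, DNA damage checkpoint and repair, p53 targets, MYC and ribosome biogenesis, ERK pathway output, immediate early genes, interferon-stimulated genes, NF-kB and inflammatory genes, the ATF4 stress response, the unfolded protein response, heat shock, glycolysis and hypoxia, cholesterol synthesis, apoptosis regulators, lysosome, mitochondrially encoded mRNA and cytosolic ribosomal proteins. Erythroid and megakaryocyte markers, lymphoid markers, and fibroblast and epithelial markers were meant to stand for cell types that the cultures should not hold. The lines express some of their members themselves: in KG1A PBS, TFRC lay at 1025 and 1005 CPM and ITGA2B at 269 CPM. A change in these lists is therefore no sign of foreign cells. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, adjusted over the 32 lists. Camera with a correlation estimated per list and fry were alternatives. The former differed from the preset test in more than the correlation. For myeloid transcription factors in KG1A the estimated correlation was -0.028, below the preset, yet the unadjusted camera p went from 0.00508 to 0.0369. A call lost there does not by itself show that the genes of a list vary together.

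The named genes were, per line, the 8 with the largest positive and the 8 with the largest negative log2 fold change past the threshold, with a mean log2 CPM of at least 2 in that line and both dG libraries on the same side of both PBS libraries, leaving out clones, pseudogenes, antisense and LINC names. Per list and line, up to 4 called members with the largest absolute change were added, or up to 2 of the highest mean CPM where none was called. The rule also took the 5 largest differences in each direction between the lines, the 6 genes in each direction called the same way in both lines with the largest smaller change, the 4 largest in each direction between the lines in PBS, and 16 genes given whatever their values (MYC, CD34, KIT, ITGAM, CD14, RRM1, RRM2, RRM2B, SAMHD1, DCK, DGUOK, PNP, CDKN1A, CEBPA, SPI1 and DUSP6). Fold changes of genes with 3 or fewer counts in a group depend on the prior count. List medians were therefore also computed from pooled counts with such groups set to the floor of 3 counts, leaving out members at or under it in both groups, a measure chosen after the data were seen.

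For the estimated correlation and fry, the residuals of each gene were placed on a common basis. The decomposition inside limma gave residual signs that changed with the numerical library in use, and with them the lists near the threshold. This basis was chosen after results had been seen, because it gave identical values on every numerical setting tried. Lists with an adjusted p just above the threshold under an estimated correlation are borderline for that reason.

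The alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors in edgeR, library size alone, other filters on low counts, the RPKM values (limma on log2 of RPKM plus 1 or plus 0.1), each line fitted alone, the replicate number as a block, stricter thresholds, and each library left out in turn. Where a group was left with 1 library, that library was assumed to vary like the other groups. A restriction to genes at 1 CPM or more in at least 2 libraries of the compared line was added after the data were seen. The edgeR steps were tested on simulated counts of 17980 genes with known changes, set in 50 genes at each fold. Far fewer genes were changed than were called in the data, so the false calls apply to sparse changes only. In the simulation of the KG1A comparison, 20% of genes changed 1.1-fold, 80% of those changed 1.25-fold, 98% of those changed 1.5-fold and 100% of those changed 2-fold were recovered, with 5 false calls among 154. For U937 the shares were 22%, 72%, 98% and 100%, with 8 false calls among 154. The list test was checked on simulated counts of 17978 genes in the KG1A comparison, where a list of 30 genes shifted by 0.3 (log2) was called and 0 of 31 unshifted lists were called. Simulated genes were drawn independently of each other, whereas the correlation estimated for the real lists reached 0.51. This check therefore does not cover false calls of lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.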

Results

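The series asked how acute myeloid leukaemia cells answer a disturbance of their deoxynucleotide pools, and whether this releases a block in their maturation. KG1A is a human line of immature leukaemic cells that carry the stem cell antigen CD34, and U937 is a human line of monoblast character. Each line was treated with 10 mM of a compound that the labels call dG, or with PBS as vehicle, and its mRNA was sequenced. There were 2 libraries per line and treatment, 8 in all. The totals were 22659210 and 28524002 counts for KG1A in PBS and 28794115 and 25361768 in dG. For U937 they were 31135338 and 24404511 in PBS and 23921246 and 21053724 in dG. Levels are in CPM, counts scaled to a common library size after TMM normalization. Replicates differed by more than counting noise (chi-square per gene 1.8 to 2.2), with correlations of log2 CPM across genes of at least 0.995. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The share of counts from mitochondrially encoded genes was 9.15% ± 0.05 (SD, n = 2) in KG1A PBS and 8.15% ± 0.20 in KG1A dG, and 9.80% ± 0.04 in U937 PBS and 8.05% ± 0.18 in U937 dG.

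The first comparison asked what dG changed in KG1A. ITGAM, which encodes the CD11b integrin subunit of maturing myeloid cells, rose from 1.63 ± 0.03 to 12.7 ± 0.41 CPM (mean ± SD, n = 2), a log2 fold change of 2.96 ± 0.13. ITGAX, the CD11c subunit, rose by 3.43 ± 0.24. MYC, a transcription factor that drives growth (ENSG00000136997, chromosome 8, 127735434 to 127741434 in GRCh38), fell from 516 ± 3.51 to 409 ± 9.54 CPM, a log2 fold change of -0.33 ± 0.03. CD34 rose by 0.35 ± 0.03, from 931 to 1191 CPM (adjusted p = 0.111 with RPKM at a pseudocount of 0.1). The cell cycle inhibitor CDKN1A rose by 1.98 ± 0.22, from 0.922 to 3.62 CPM. In all, 5413 genes were higher and 3581 lower in dG, which is 49.1% of those tested, and 1033 and 211 of them changed at least 2-fold.

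Under the rule for named genes, which asks for a mean log2 CPM of at least 2, the genes with the largest rises in KG1A included SELP (3.68 ± 0.15), the adhesion receptor P-selectin, and ITGB3 (3.41 ± 0.12), an integrin subunit of platelets. ADM, a hypoxia-induced peptide hormone, rose by 2.92 ± 0.11. CPA3, the carboxypeptidase of mast cell granules, rose by 2.52 ± 0.04, from 41.8 to 239 CPM. MRC2, TNXB and CFAP161 also rose, by 2.95 ± 0.13, 2.85 ± 0.13 and 2.48 ± 0.06. NDST3, a heparan sulfate sulfotransferase, had the largest fall under the rule for named genes, at -2.08 ± 0.11. TFRC, the transferrin receptor, fell by 1.39 ± 0.03 on the log2 scale, from 1015 to 388 CPM. The other large falls were those of FDXACB1, C11orf71, ALG14, TANGO6 and the ribosome assembly factors UTP20 and RRP12, between -1.53 and -1.27.

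Among the gene lists in KG1A, MYC and ribosome biogenesis moved most uniformly. Of its 40 measured genes 39 fell and 0 rose, with a median log2 fold change of -0.55 (camera adjusted p = 1.8e-27). This call held under an estimated correlation (adjusted p = 0.0207 with an estimated correlation), and it was the only KG1A list for which that was so. Members that fell included UTP20 (-1.31 ± 0.06), ODC1 (-1.16 ± 0.04), the rate-limiting enzyme of polyamine synthesis, and EBNA1BP2 (-1.15 ± 0.05). Mitochondrially encoded mRNA fell in 11 of 13 genes and rose in 1, at a median of -0.20 (camera adjusted p = 3.11e-06, adjusted p = 0.222 with an estimated correlation), together with the lower mitochondrial share of the dG libraries. Purine synthesis and salvage fell (4 higher, 11 lower of 20, median -0.13, camera adjusted p = 0.0106, adjusted p = 0.112 with an estimated correlation). IMPDH2, the rate-limiting enzyme of guanine nucleotide synthesis, changed by -0.46 ± 0.03 and the salvage enzyme APRT by -1.03 ± 0.06. Cholesterol synthesis fell (2 higher, 16 lower of 23, median -0.26, camera adjusted p = 1.41e-05, adjusted p = 0.099 with an estimated correlation), with HMGCS1 at -0.81 ± 0.04. Heat shock genes fell as a list (5 higher, 7 lower of 14, median -0.21, or -0.11 over the 13 members above 3 counts, camera adjusted p = 0.0139, adjusted p = 0.124 with an estimated correlation). The mitochondrial chaperonin genes HSPD1 (-0.71 ± 0.03) and HSPE1 (-0.73 ± 0.06) fell, while HSPB1 rose by 0.96 ± 0.10. The unfolded protein response list fell (5 higher, 8 lower of 15, median -0.11, camera adjusted p = 0.0365, adjusted p = 0.334 with an estimated correlation), with the endoplasmic reticulum chaperone HSPA5 at -0.79 ± 0.03, although EDEM1 rose by 0.67 ± 0.04.

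In KG1A, G2/M and mitosis genes were higher in 28 and lower in 1 of 32, with a median of 0.42 (camera adjusted p = 2.47e-11, adjusted p = 0.0795 with an estimated correlation), among them TOP2A (0.68 ± 0.03) and NUSAP1 (0.71 ± 0.03). G1/S cyclins and E2F genes were higher in 17 and lower in 3 of 23 (median 0.40, camera adjusted p = 5.51e-05, adjusted p = 0.099 with an estimated correlation). This list also holds inhibitors of the cycle, and CDKN1A and CDKN2D (1.12 ± 0.08) were among its largest rises beside E2F7 (1.05 ± 0.06). DNA damage checkpoint and repair genes rose (20 higher, 4 lower of 32, median 0.21, camera adjusted p = 0.00435, adjusted p = 0.153 with an estimated correlation). FANCI rose by 0.66 ± 0.03 and CHEK2 by 0.56 ± 0.06. The DNA replication list showed no balance either way (14 higher, 10 lower of 35, median -0.01, mean 0.04, camera adjusted p = 0.879). Glycolysis and hypoxia genes rose (21 higher, 0 lower of 26, median 0.61, camera adjusted p = 3.72e-09, adjusted p = 0.099 with an estimated correlation). ADM, PFKFB4 (2.44 ± 0.08), ENO2 (1.83 ± 0.10) and BNIP3 (1.53 ± 0.06) rose most.

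In KG1A, interferon-stimulated genes were higher in 23 and lower in 1 of 34 (median 0.48, camera adjusted p = 1.54e-05, adjusted p = 0.0703 with an estimated correlation). XAF1 rose by 1.21 ± 0.09 and BST2 by 0.96 ± 0.04. NF-kB and inflammatory genes were higher in 13 and lower in 0 of 26 (median 0.54, camera adjusted p = 0.000271, adjusted p = 0.099 with an estimated correlation). ICAM1 rose by 1.82 ± 0.08 and TNFAIP3, an inhibitor of the pathway, by 1.62 ± 0.05. ERK pathway output genes were higher in 13 and lower in 1 of 17 (median 0.63, camera adjusted p = 0.000571, adjusted p = 0.099 with an estimated correlation). DUSP6, a phosphatase induced by ERK, rose by 1.22 ± 0.04 from 137 to 318 CPM. Immediate early genes (8 higher, 0 lower of 19, median 0.28, camera adjusted p = 0.0279) and the ATF4 stress response (15 higher, 4 lower of 24, median 0.21, camera adjusted p = 0.0106) rose, with adjusted p = 0.144 and adjusted p = 0.337 with an estimated correlation. PHGDH (1.56 ± 0.08) and ASNS (1.12 ± 0.06), enzymes of serine and asparagine synthesis, were among the risen ATF4 genes. Apoptosis regulators (16 higher, 3 lower of 27, median 0.24, camera adjusted p = 0.0106) and lysosome genes (21 higher, 2 lower of 30, median 0.29, camera adjusted p = 0.000271) rose, with adjusted p = 0.244 and adjusted p = 0.334 with an estimated correlation. Both protective members, such as BIRC3 (1.34 ± 0.04), and the death receptor gene TNFRSF10B (0.57 ± 0.07) were among the risen apoptosis regulators.

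Lineage lists in KG1A were mixed. Stem and progenitor genes rose (19 higher, 0 lower of 26, median 0.32, camera adjusted p = 1.1e-05, adjusted p = 0.0703 with an estimated correlation). ADGRG1 rose by 1.05 ± 0.07 and NYNRIN by 1.81 ± 0.14. Myeloid transcription factors rose (10 higher, 0 lower of 22, median 0.45, camera adjusted p = 0.0106, adjusted p = 0.112 with an estimated correlation). ZEB2 rose by 0.75 ± 0.04 and JUNB by 0.63 ± 0.08. Monocyte and macrophage markers were higher in 9 and lower in 1 of 31 without a call for the list (median 0.69, camera adjusted p = 0.11), and the 18 of them with over 3 counts in at least 1 KG1A group had a median of 1.18. The lower member was CD14, from 0.509 to 0.152 CPM (-1.69 ± 0.52, adjusted p = 0.00659), whose call ended without PBS replicate 1 (adjusted p = 0.1) or without dG replicate 1 (adjusted p = 0.0742). Late neutrophil markers (5 higher, 0 lower of 13, camera adjusted p = 0.0922), primary granule genes (5 higher, 2 lower of 14, camera adjusted p = 0.258) and phagocyte oxidase genes (3 higher, 0 lower of 6, camera adjusted p = 0.258) were not called as lists, although CSF3R rose by 1.20 ± 0.07 and NKG7 by 1.36 ± 0.06. The monocyte, late neutrophil and primary granule lists were far higher in U937 in PBS (median log2 differences 5.22, 5.95 and 8.34). Reads of 51 U937-specific genes numbered 51 and 85 in the KG1A PBS libraries and 138 and 100 in the dG libraries. For members near 0 counts in KG1A, a rise was therefore not told apart from trace reads of U937. With library size alone the monocyte and late neutrophil lists were called (adjusted p = 0.0351 and 0.0448). The monocyte list was also called without U937 dG replicate 1 or 2 (adjusted p = 0.0297 and 0.0293). The late neutrophil list was called without KG1A PBS replicate 1 (adjusted p = 0.0358), KG1A dG replicate 1 (adjusted p = 0.0339) or any U937 library (adjusted p = 0.019 to 0.0464). None of the 10 MHC class II genes was called (camera adjusted p = 0.755), and their KG1A means did not exceed 0.263 CPM. HLA-DMB was called without KG1A dG replicate 1 (adjusted p = 0.0391). SPI1 (0.97 ± 0.45, adjusted p = 0.0708, or 0.0301 with RPKM at a pseudocount of 0.1) and KIT (0.32 ± 0.28, adjusted p = 0.373) did not pass the test. CEBPA passed it at 0.22 ± 0.07, but not without KG1A PBS replicate 1 (adjusted p = 0.134), KG1A dG replicate 1 (adjusted p = 0.427) or U937 dG replicate 1 or 2 (adjusted p = 0.115 and 0.114). The CEBPA call also ended with library size alone (adjusted p = 0.0894), no filter (adjusted p = 0.161), KG1A fitted alone (adjusted p = 0.139) and each RPKM setting (adjusted p = 0.153 to 0.307).

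Genes of the dNTP pathway itself went both ways in KG1A (8 higher, 9 lower of 24, median 0.06, mean -0.02, camera adjusted p = 0.839). RRM2, the regulated subunit of ribonucleotide reductase, rose by 0.71 ± 0.03 and the large subunit RRM1 by 0.20 ± 0.03 (adjusted p = 0.0659 with unfiltered RPKM). The mitochondrial deoxyguanosine kinase gene DGUOK fell by 0.39 ± 0.06 on the log2 scale. RRM2B (0.09 ± 0.04, adjusted p = 0.0893), SAMHD1 (0.12 ± 0.13, adjusted p = 0.501), DCK (0.05 ± 0.04, adjusted p = 0.348) and PNP (0.09 ± 0.04, adjusted p = 0.0762) did not pass the test, although PNP did without PBS replicate 2 (adjusted p = 0.0300) or dG replicate 2 (adjusted p = 0.0158). The lists of p53 targets (11 higher, 5 lower of 25, camera adjusted p = 0.185), replication-dependent histones (2 higher, 0 lower of 13, camera adjusted p = 0.995) and cytosolic ribosomal proteins (5 higher, 12 lower of 30, camera adjusted p = 0.0761) were not called. The ribosomal protein list was called without KG1A PBS replicate 1 (adjusted p = 0.00836), KG1A dG replicate 1 (adjusted p = 0.00963), or U937 dG replicate 1 or 2 (adjusted p = 0.0023 and 0.00231), with library size alone (adjusted p = 0.0023) and with DESeq2's size factors (adjusted p = 0.0433). The lists meant for other cell types were not called either: erythroid and megakaryocyte (4 higher, 1 lower of 6, camera adjusted p = 0.223), lymphoid (5 higher, 1 lower of 13, camera adjusted p = 0.129), and fibroblast and epithelial (1 higher, 1 lower of 4, camera adjusted p = 0.879). Adjusted over the list alone, counts equalled those over all genes except for purine synthesis (5 and 11), stem and progenitor genes (20 and 0), G2/M (29 and 1), histones (0 and 0), DNA damage (21 and 6), interferon-stimulated genes (23 and 2), the unfolded protein response (5 and 9) and lymphoid markers (6 and 2). The balance of rises and falls depended on the scaling: library size alone gave 4584 higher and 4435 lower, and the RPKM values with a pseudocount of 1 gave 3677 and 4055. In total, 4584 genes were higher and 3581 lower under each of 3 size factors. With TMM the balance also moved, to 4605 higher and 4393 lower with KG1A fitted alone and 4427 and 4279 with no filter.

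**Figure D1:**
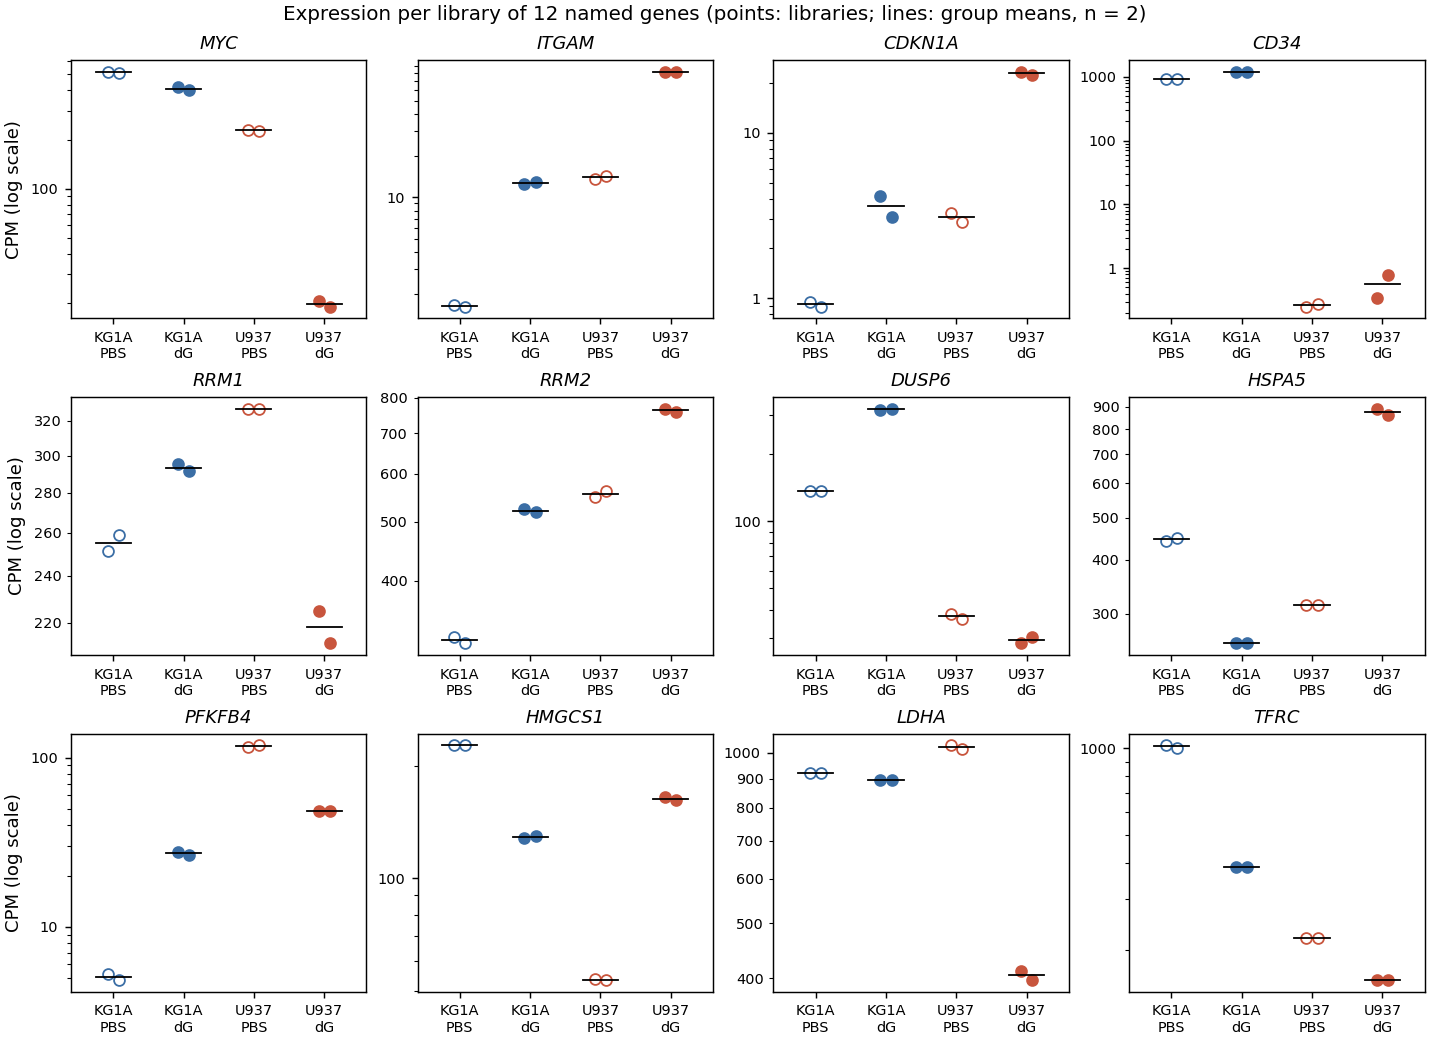
CPM on a log scale for 12 named genes in each of the 8 libraries, with points for libraries and lines for the means of 2 libraries per group. MYC fell from 227 to 19.9 CPM in U937 and from 516 to 409 CPM in KG1A, ITGAM rose in both lines, and HSPA5, PFKFB4, HMGCS1, DUSP6 and RRM1 moved in opposite directions between the lines.

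In U937, MYC fell from 227 ± 1.08 to 19.9 ± 1.18 CPM in dG (mean ± SD, n = 2), a log2 fold change of -3.51 ± 0.05. MHC class II genes, which present antigen to T cells, all rose, with HLA-DRA going from 198 to 973 CPM (2.30 ± 0.04). ITGAM rose from 13.9 ± 0.35 to 81.2 ± 0.08 CPM (2.55 ± 0.06) and ITGAX from 7.17 to 81.8 CPM (3.52 ± 0.08). CDKN1A rose by 2.88 ± 0.12, from 3.08 to 22.8 CPM. Of the genes tested, 5940 were higher and 5772 lower, which is 64.0%, and 1778 and 1417 of them changed at least 2-fold.

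Among genes with a mean log2 CPM of at least 2 in U937 and the other conditions of the rule for named genes, the largest rises were those of MS4A14 (5.90 ± 0.14), the collagenase gene MMP1 (5.53 ± 0.05, from 11.1 to 513 CPM), HLA-DPA1 (5.02 ± 0.15), the acetylcholine receptor subunit CHRNA3 (4.90 ± 0.14), SLC26A11 (3.90 ± 0.14), PAX8 (3.87 ± 0.08), MS4A4A (3.85 ± 0.09) and the inducible chaperone HSPA1B (3.78 ± 0.07). Under the same rule the largest falls after MYC were in the arginine methyltransferase PRMT6 (-3.20 ± 0.15), WDR4 (-2.98 ± 0.12), GPATCH4 (-2.90 ± 0.08), UTP20 (-2.68 ± 0.08), FERMT1 (-2.66 ± 0.08), EBNA1BP2 (-2.62 ± 0.05) and the pseudouridine synthase PUS7 (-2.51 ± 0.07).

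In U937, MYC and ribosome biogenesis was lower in 38 and higher in 1 of 40, with a median of -1.31 (camera adjusted p = 2.11e-20, adjusted p = 0.0369 with an estimated correlation). Purine synthesis and salvage was lower in 17 and higher in 2 of 20 (median -0.64, camera adjusted p = 8.38e-07, adjusted p = 0.0395 with an estimated correlation). PFAS changed by -2.24 ± 0.07, PAICS by -1.56 ± 0.03 and IMPDH2 by -1.34 ± 0.04. Both lists thus passed under either correlation. DNA replication genes were lower in 29 and higher in 4 of 35 (median -0.50, camera adjusted p = 2.53e-09, adjusted p = 0.0666 with an estimated correlation). The polymerase subunit POLA1 changed by -2.09 ± 0.04 and MCM5 by -1.06 ± 0.04. Cytosolic ribosomal proteins (0 higher, 28 lower of 30, median -0.39, camera adjusted p = 1.01e-10) and mitochondrially encoded mRNA (1 higher, 12 lower of 13, median -0.46, camera adjusted p = 1.03e-06) fell, with adjusted p = 0.172 and adjusted p = 0.168 with an estimated correlation. MT-CYB changed by -1.46 ± 0.03 and MT-ND1 by -1.31 ± 0.03, beside the lower mitochondrial share of the U937 dG libraries. Glycolysis and hypoxia genes were lower in 21 and higher in 5 of 26 (median -0.56, camera adjusted p = 4.55e-07, adjusted p = 0.0951 with an estimated correlation). LDHA, lactate dehydrogenase, changed by -1.34 ± 0.03, PFKFB4 by -1.27 ± 0.05 and enolase ENO1 by -1.08 ± 0.03, whereas the angiogenic factor VEGFA rose by 1.98 ± 0.03. DNA damage checkpoint and repair genes were lower in 20 and higher in 9 of 32 (median -0.16, camera adjusted p = 0.0169, adjusted p = 0.17 with an estimated correlation), a call that ended with DESeq2's size factors (adjusted p = 0.0546).

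In U937, MHC class II presentation was higher in 10 of 10 (median 3.59, camera adjusted p = 2.05e-08, adjusted p = 0.0395 with an estimated correlation). HLA-DPB1 rose by 4.60 ± 0.20, the transactivator CIITA by 0.88 ± 0.05 and CD74 by 1.73 ± 0.03. Interferon-stimulated genes were higher in 25 and lower in 2 of 34 (median 1.14, or 0.94 over the members with more than 3 counts, camera adjusted p = 7.85e-07, adjusted p = 0.0395 with an estimated correlation). IRF9 rose by 3.38 ± 0.21 and IFI6 by 2.88 ± 0.05. NF-kB and inflammatory genes were higher in 22 and lower in 1 of 26 (median 1.15, camera adjusted p = 6.91e-08, adjusted p = 0.0528 with an estimated correlation). CCL3 rose by 3.40 ± 0.17 and IL1B by 2.84 ± 0.16. Monocyte and macrophage markers were higher in 21 and lower in 3 of 31 (median 1.02, camera adjusted p = 4.53e-06, adjusted p = 0.0735 with an estimated correlation). The complement receptor C5AR1 rose by 4.34 ± 0.19 and CEBPB by 1.91 ± 0.05. CD14 had 3 counts in PBS and 2 in dG (adjusted p = 0.922). Late neutrophil markers (9 higher, 1 lower of 13, median 1.15, or 2.14 over the 11 with more than 3 counts, camera adjusted p = 0.000896), primary granule genes (11 higher, 2 lower of 14, median 0.78, camera adjusted p = 0.000113) and phagocyte oxidase genes (5 higher, 0 lower of 6, median 0.75, camera adjusted p = 0.00568) rose. Their values were adjusted p = 0.104, adjusted p = 0.165 and adjusted p = 0.179 with an estimated correlation. Among these genes the collagenase MMP8 rose by 2.65 ± 0.10, CTSG by 1.17 ± 0.03 and the oxidase subunit CYBB by 1.71 ± 0.14, and the protease gene PRTN3 fell by 1.02 ± 0.04 on the log2 scale. Lysosome genes were higher in 29 and lower in 0 of 30 (median 1.06, camera adjusted p = 1.44e-17, adjusted p = 0.0735 with an estimated correlation). The cholesterol transporter NPC1 rose by 1.88 ± 0.03 and GLB1 by 1.61 ± 0.03.

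The unfolded protein response in U937 was higher in 14 and lower in 0 of 15 (median 0.75, camera adjusted p = 1.12e-08, adjusted p = 0.0677 with an estimated correlation). DNAJB9 rose by 2.17 ± 0.07 and HSPA5 by 1.48 ± 0.03. Cholesterol synthesis was higher in 18 and lower in 1 of 23 (median 0.56, camera adjusted p = 3.08e-06, adjusted p = 0.0735 with an estimated correlation). MSMO1 rose by 1.99 ± 0.04 and HMGCS1 by 1.61 ± 0.04. G2/M and mitosis genes were higher in 25 and lower in 5 of 32 (median 0.34, camera adjusted p = 1.77e-05, adjusted p = 0.0992 with an estimated correlation). The phosphatase CDC25B rose by 1.37 ± 0.04 and CDK1 by 0.66 ± 0.03. Immediate early genes (12 higher, 2 lower of 19, median 0.41, camera adjusted p = 0.00182) and myeloid transcription factors (14 higher, 4 lower of 22, median 0.18, camera adjusted p = 0.00359) rose, with KLF6 in both lists at 1.94 ± 0.04, and each had adjusted p = 0.0735 with an estimated correlation. Apoptosis regulators (17 higher, 5 lower of 27, median 0.44, camera adjusted p = 0.00394) and p53 targets (16 higher, 4 lower of 25, median 0.36, camera adjusted p = 0.0364) rose, with adjusted p = 0.168 and adjusted p = 0.129 with an estimated correlation. Among them were the survival gene BCL2A1 (1.79 ± 0.03), the death gene BMF (1.76 ± 0.06) and TP53INP1 (3.64 ± 0.35). Replication-dependent histones were higher in 9 and lower in 1 of 13 (median 1.63, camera adjusted p = 0.0169, adjusted p = 0.11 with an estimated correlation), with HIST1H2AC going from 0.857 to 11.6 CPM. RNAs that lack a poly(A) tail moved beside them: of 40 measured small nuclear, small nucleolar, Cajal body and signal recognition RNAs, 21 were higher and 1 lower in U937 dG, at a median of 0.97, against 6 higher and 6 lower in KG1A dG. The list of fibroblast and epithelial markers was called with 3 of 4 genes higher (median 1.34, or 0.92 over the 3 with more than 3 counts, camera adjusted p = 0.0417, adjusted p = 0.17 with an estimated correlation), namely COL1A1 (1.76 ± 0.20), FN1 (0.92 ± 0.15) and the endothelial and myeloid gene PECAM1 (0.92 ± 0.04). This call ended without any of 7 of the 8 libraries, the exception being U937 PBS replicate 2, with adjusted p between 0.067 and 0.119, and with DESeq2's size factors (adjusted p = 0.0597).

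The dNTP list was not called in U937 (9 higher, 11 lower of 24, median -0.16, camera adjusted p = 0.498). RRM1 fell by 0.58 ± 0.03 on the log2 scale while RRM2 rose by 0.46 ± 0.03. RRM2B, the subunit induced by p53, rose by 0.39 ± 0.05, the dNTP hydrolase SAMHD1 by 0.79 ± 0.10 and the kinase DCK by 0.35 ± 0.04. NME1 (-1.48 ± 0.07) fell, and so did PNP, which cleaves deoxyguanosine, at -0.28 ± 0.05. DGUOK did not pass the test (0.09 ± 0.05, adjusted p = 0.145) but did without dG replicate 2 (adjusted p = 0.0173), with DESeq2's size factors (adjusted p = 0.00357), with no filter (adjusted p = 0.0265) and with RPKM at a pseudocount of 1 (adjusted p = 0.0499). Stem and progenitor genes (9 higher, 5 lower of 26, camera adjusted p = 0.685), G1/S cyclins and E2F genes (12 higher, 8 lower of 23, camera adjusted p = 0.498), ERK pathway output (8 higher, 5 lower of 17, camera adjusted p = 0.498), the ATF4 stress response (12 higher, 6 lower of 24, camera adjusted p = 0.116) and heat shock genes (6 higher, 8 lower of 14, median -0.21, mean 0.41, camera adjusted p = 0.498) were not called. Within these lists SOX4 rose by 1.64 ± 0.05, DUSP6 fell by 0.36 ± 0.06 on the log2 scale and the stress gene PPP1R15A rose by 2.25 ± 0.04. Erythroid and megakaryocyte markers (2 higher, 2 lower of 6, median 0.07, mean 0.67, test downward, camera adjusted p = 0.862) and lymphoid markers (4 higher, 3 lower of 13, camera adjusted p = 0.855) were not called. KG1A-specific genes held trace reads in U937, at 0.0205% and 0.0208% of their KG1A level in PBS and 0.0363% and 0.0525% in dG. CD34, at 932 and 931 CPM in the KG1A PBS libraries, lay at a similar trace level in U937. Its values there were therefore not told apart from reads of KG1A. CD34 lay at 0.265 and 0.561 CPM (1.04 ± 0.42, adjusted p = 0.0378), a call that ended without PBS replicate 1 (adjusted p = 0.153), PBS replicate 2 (adjusted p = 0.0767) or dG replicate 2 (adjusted p = 0.585), with library size alone (adjusted p = 0.0545), with limma-voom (adjusted p = 0.0637) and with each RPKM setting. KIT did not pass (adjusted p = 0.486), CEBPA rose by 0.16 ± 0.04 (adjusted p = 0.0503 with library size alone and 0.0606 with unfiltered RPKM), and SPI1 fell by 0.19 ± 0.06 on the log2 scale, a call that ended without dG replicate 2 (adjusted p = 0.468), with DESeq2's size factors (adjusted p = 0.116), with no filter (adjusted p = 0.078), with DESeq2 (adjusted p = 0.43) and with each RPKM setting. Adjusted over the list alone, counts equalled those over all genes except for primary granule genes (11 and 3) and NF-kB and inflammatory genes (23 and 1). The balance of directions depended on the scaling: DESeq2's size factors gave 6697 higher and 4900 lower, and library size alone 5286 and 6495. Under each of 3 size factors, 5286 genes were higher and 4900 lower.

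**Figure D2:**
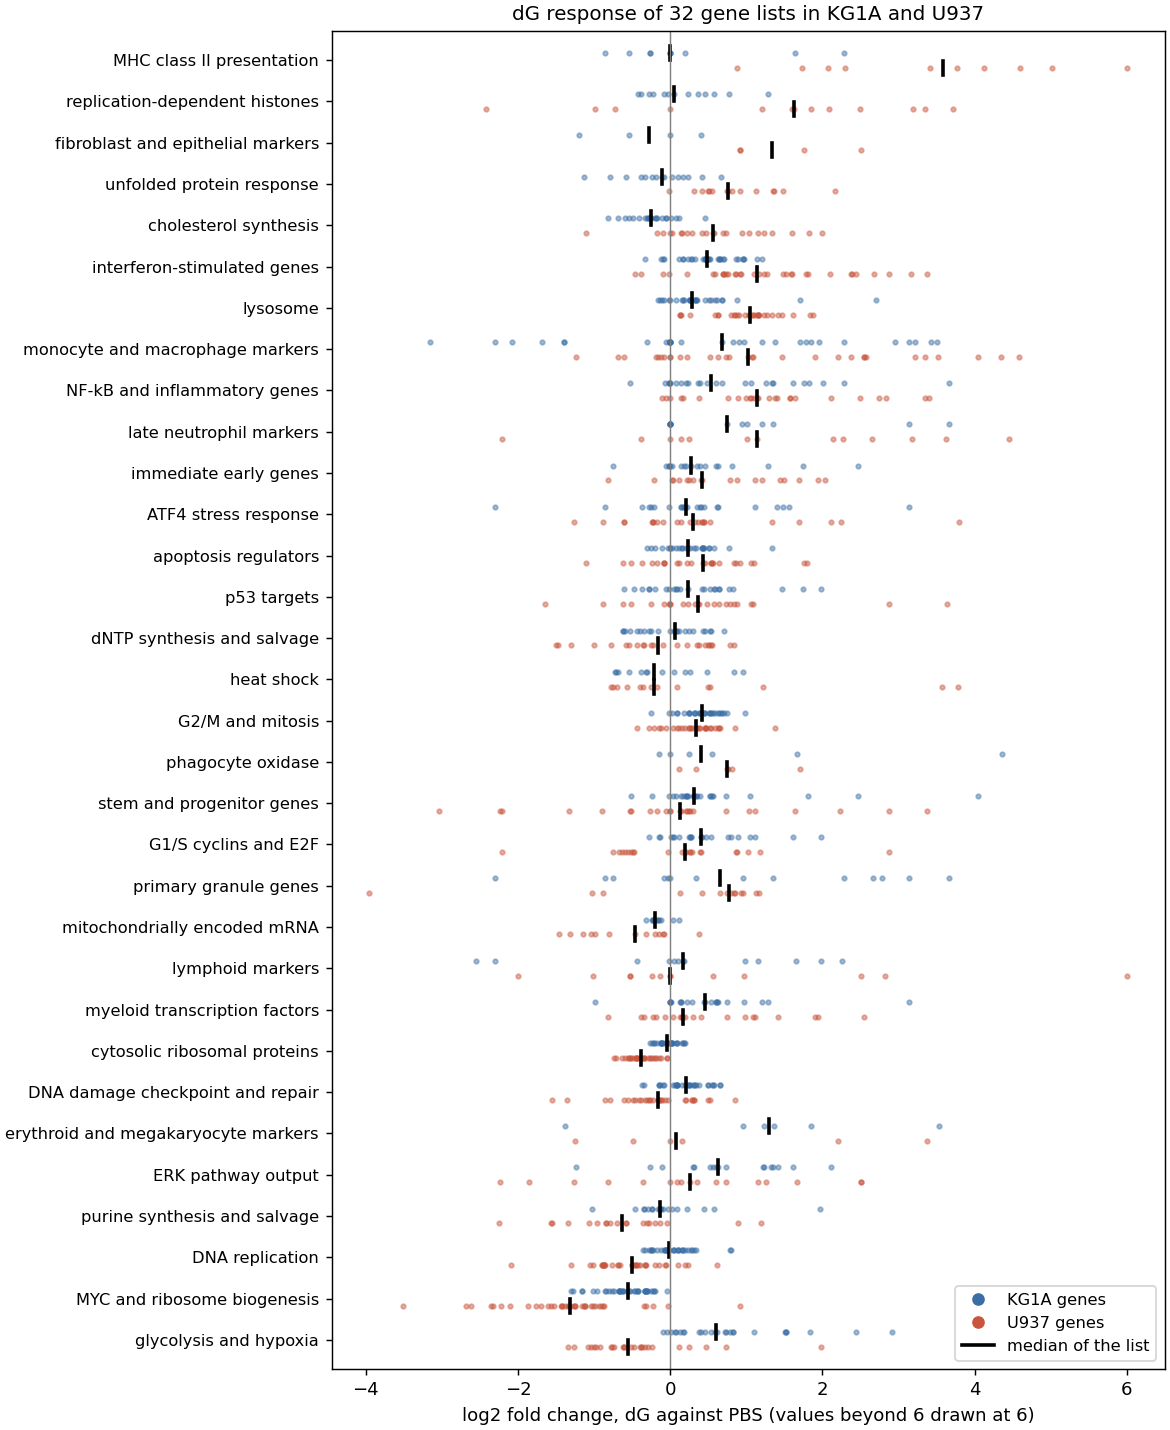
Log2 fold changes of dG against PBS for the measured genes of the 32 gene lists in KG1A (blue) and U937 (red), with a point per gene, a black bar at the median of the list, and values beyond 6 drawn at 6. MHC class II presentation had a median of 3.59 in U937, MYC and ribosome biogenesis lay below 0 in both lines (-0.55 and -1.31), and glycolysis and hypoxia lay at 0.61 in KG1A and -0.56 in U937.

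Whether the lines answered dG differently was tested as the U937 effect minus the KG1A effect. Glycolysis and hypoxia, cholesterol synthesis, the unfolded protein response, and DNA damage checkpoint and repair were called in opposite directions in the lines by camera with the preset correlation. With an estimated correlation none of these 8 calls within a line held (adjusted p = 0.0677 to 0.334 with an estimated correlation). HMGCS1, the first committed enzyme of the sterol pathway, went from 226 to 129 CPM in KG1A and from 53.6 to 163 CPM in U937, and HSPA5 went from 446 to 257 CPM in KG1A and from 315 to 879 CPM in U937. PFKFB4, a regulator of glycolysis, went from 5.05 to 27.2 CPM in KG1A and from 117 to 48.6 CPM in U937. MYC fell more in U937, by 3.17 ± 0.06 on the log2 scale. Of the 10 genes with the largest differences under the rule for named genes, MACC1 (8 to 214 counts) and GBP2 (8 to 216 counts) rose in U937, while NRIP1, LPAR6, COBLL1, GRB10 and MEIS1 had 17 counts or fewer in each group of 1 of the lines. The effects differed for 8071 genes (44.1%), 3230 with a higher and 4841 with a lower U937 effect, and 737 and 1289 of them differed at least 2-fold.

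Of the 32 lists, 15 differed between the lines. Glycolysis and hypoxia had a lower U937 effect in 24 and a higher in 1 of 26 genes (median difference -1.09, camera adjusted p = 3.51e-17). Cholesterol synthesis had a higher U937 effect in 20 and a lower in 1 of 23 (0.78, camera adjusted p = 3.29e-14), and so did the unfolded protein response in 14 of 15, with 1 lower (1.13, camera adjusted p = 4.91e-14). MYC and ribosome biogenesis (3 higher, 33 lower of 40, median -0.82, camera adjusted p = 1.49e-13), DNA replication (2 higher, 32 lower of 35, median -0.61, camera adjusted p = 9.68e-13) and purine synthesis and salvage (1 higher, 14 lower of 20, median -0.60, camera adjusted p = 6.24e-07) had lower U937 effects. Interferon-stimulated genes had higher ones (21 higher, 4 lower of 34, median 0.76, camera adjusted p = 8.76e-06). These 7 lists had adjusted p = 0.033 each with an estimated correlation.

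The other 8 lists lost their call under an estimated correlation. For histones and MHC class II presentation this was so although the estimated correlation (-0.042 and -0.012) lay below the preset 0.01. Higher U937 effects were found for lysosome genes (25 higher, 2 lower of 30, median 0.65, camera adjusted p = 6.11e-14, adjusted p = 0.119 with an estimated correlation) and for histones (8 higher, 0 lower of 13, median 1.98, camera adjusted p = 0.00463, adjusted p = 0.0967 with an estimated correlation), beside the RNAs without a poly(A) tail, of which 11 were higher and 0 lower of 40. MHC class II presentation differed as a list (median 2.75, camera adjusted p = 0.000171, adjusted p = 0.055 with an estimated correlation), although 2 of its 10 genes passed individually: HLA-DPA1, HLA-DPB1 and HLA-DQA1 had 0 counts in KG1A, and the 4 members with more than 3 counts in both lines had a median of 2.31. The monocyte and macrophage call (7 higher, 5 lower of 31, median 0.64, camera adjusted p = 0.0443, adjusted p = 0.33 with an estimated correlation) included genes near 0 counts in KG1A: the 15 members with more than 3 counts in both lines had a median of 0.08, without a camera test of their own. It ended without either dG library of U937 (adjusted p = 0.214 and 0.19), U937 PBS replicate 1 (adjusted p = 0.0595), KG1A PBS replicate 1 (adjusted p = 0.0818) or either KG1A dG library (adjusted p = 0.0589 and 0.0552), and with DESeq2's size factors (adjusted p = 0.138). Lower U937 effects were found for cytosolic ribosomal proteins (0 higher, 26 lower of 30, median -0.32, camera adjusted p = 5.37e-10, adjusted p = 0.319 with an estimated correlation) and for DNA damage checkpoint and repair (4 higher, 23 lower of 32, median -0.34, camera adjusted p = 1.13e-05, adjusted p = 0.0758 with an estimated correlation). Mitochondrially encoded mRNA (2 higher, 8 lower of 13, median -0.29, camera adjusted p = 0.0004, adjusted p = 0.342 with an estimated correlation) differed likewise, but not without U937 dG replicate 2 (adjusted p = 0.0897). G1/S cyclins and E2F genes (3 higher, 11 lower of 23, median -0.24, camera adjusted p = 0.0428, adjusted p = 0.301 with an estimated correlation) were no longer called without KG1A dG replicate 1, U937 PBS replicate 1 or either U937 dG library (adjusted p = 0.053, 0.0527, 0.143 and 0.19), or with DESeq2's size factors (adjusted p = 0.113).

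The remaining 17 lists did not differ past the threshold, with camera adjusted p from 0.0698 (fibroblast and epithelial markers) to 0.784. Of these, the fibroblast and epithelial list passed with a replicate block (adjusted p = 0.044) and apoptosis regulators without U937 dG replicate 1 (adjusted p = 0.042). The dNTP list was among them (7 higher, 9 lower of 24, camera adjusted p = 0.513). For 6 of these lists the test pointed upward while the median lay below 0, namely primary granule genes (-0.29, mean -0.74), phagocyte oxidase (-0.17, mean -0.37), myeloid transcription factors (-0.31), heat shock (-0.07, mean 0.48), erythroid and megakaryocyte markers (-0.36, mean -0.59) and lymphoid markers (-0.31, mean 0.50). Single genes still differed: RRM1 by -0.79 ± 0.05, DUSP6 by -1.58 ± 0.07 and CEBPB by 1.76 ± 0.08. Adjusted over the list alone, counts changed for monocyte markers (7 and 4), histones (8 and 1), DNA damage (4 and 24), mitochondrially encoded mRNA (2 and 9) and ribosomal proteins (0 and 27) among the called lists. The balance of directions depended on the scaling: DESeq2's size factors moved the median difference over all genes by 0.10 and gave 4021 genes with a higher and 3898 with a lower U937 effect. Under each of 3 size factors, 3132 genes had a higher and 3898 a lower U937 effect. With TMM and no filter on low counts the balance turned, with 4077 higher and 3490 lower.

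Part of the answer was common to both lines. ITGAM rose in both, as did MILR1 (2.20 ± 0.12 in KG1A and 2.55 ± 0.13 in U937), an inhibitory receptor of mast cells, RAPGEF3 (1.62 ± 0.13 and 3.37 ± 0.11), CLU (1.59 ± 0.11 and 1.63 ± 0.05), TNFAIP3 (1.62 ± 0.05 and 1.58 ± 0.04) and VWA5A (1.54 ± 0.09 and 2.57 ± 0.07). UTP20, ODC1, EBNA1BP2, OPN3 (-1.26 ± 0.15 and -1.14 ± 0.07), MIPEP (-1.13 ± 0.13 and -1.93 ± 0.11) and C12orf66 (-1.12 ± 0.14 and -1.46 ± 0.10) fell in both. Of the genes tested, 2815 were higher in both lines, against 1756 expected of independent lists, and 2396 were lower in both, against 1129 expected. Opposite calls were fewer than expected, with 903 genes higher in KG1A and lower in U937 (1706 expected) and 459 the other way (1162 expected). The lines shared no libraries. Over all genes tested the log2 fold changes had Pearson's r = 0.25 and Spearman's rho = 0.36, and over the 9894 genes expressed in both lines r = 0.50 and rho = 0.53, across genes, which are not independent replicates.

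**Figure D3:**
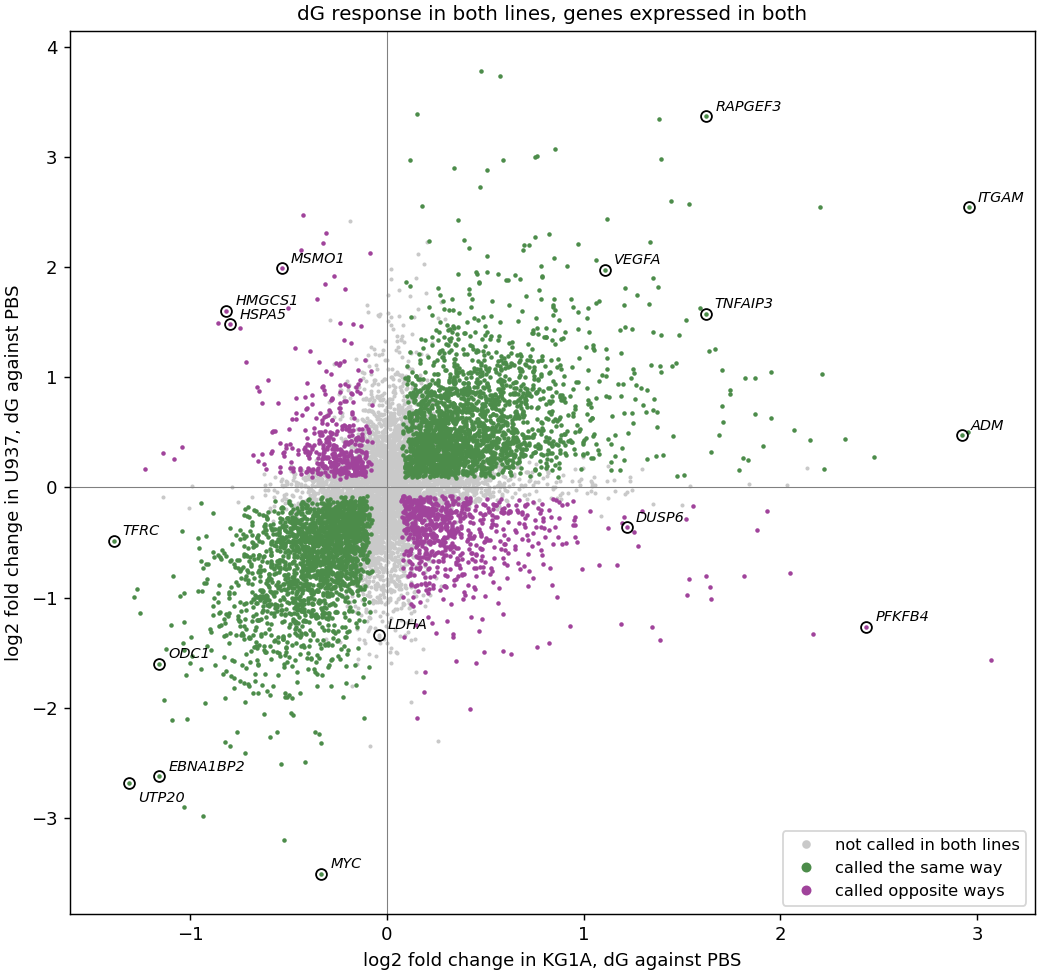
Log2 fold change of dG against PBS in KG1A (horizontal) and U937 (vertical) for the 9894 genes expressed in both lines, with green points for genes called the same way, purple for opposite calls and grey for the rest. ITGAM and TNFAIP3 lie at the upper right, UTP20 and ODC1 at the lower left, HMGCS1 and HSPA5 at the upper left, and PFKFB4 at the lower right.

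As background to these effects, the lines themselves were compared in PBS. U937 expressed the transcription factor IRF8, required for monocyte development, at 278 CPM, with 2 counts in the KG1A group, a ratio of 7264 (95% counting interval 2011 to 59988). GRB10 (1 count in KG1A, ratio 11189, 2008 to 441990), USP22 (1 count, 8823, 1583 to 348510) and GAS7 (2 counts, 6404, 1773 to 52886) were also higher in U937. KG1A expressed HGF, a growth factor for many cell types, at 612 CPM, with 3 counts in the U937 group, a ratio of 11622 (3977 to 56360). APP (29894, 5365 to 1180800) and the platelet integrin subunit ITGA2B (15323, 2750 to 605270) had 1 count each in U937. NRIP1 had 20823 counts in KG1A PBS and 0 in U937 PBS. In all, 7590 genes were higher in U937 and 7475 in KG1A, which is 82.3%. Glycolysis and hypoxia genes were higher in U937 in 26 of 26 (median 1.54, camera adjusted p = 1.46e-10), lysosome genes in 24 of 30 (camera adjusted p = 7.56e-07), myeloid transcription factors in 20 of 22 (camera adjusted p = 0.000119), monocyte markers in 23 of 31 (camera adjusted p = 0.00132), MHC class II in 10 of 10 (camera adjusted p = 0.0023), primary granule genes in 11 of 14 (camera adjusted p = 0.0031), and late neutrophil markers in 10 of 13 and G2/M genes in 23 of 32 (camera adjusted p = 0.0206 each). Stem and progenitor genes were higher in KG1A in 21 of 26 (camera adjusted p = 0.000807). None of these 9 calls held under an estimated correlation, where the lowest value was adjusted p = 0.17 with an estimated correlation.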

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

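The tests on histone genes, the test on single libraries, and the second gene set for reads of the other line with the 2 SD allowed around the bound and the values without 1 gene, were chosen after their results had been seen.

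The response to dG differed between KG1A and U937 by a test of the difference itself, and the results below were singled out for that reason. It differed for 8071 genes, in both directions. The named genes with the largest differences were NRIP1 (5.35), LPAR6 (5.30), COBLL1 (5.01), MACC1 (4.95) and GBP2 (4.40) with a higher log2 effect in U937, and GRB10 (-4.17), MEIS1 (-4.11), GATA3 (-4.04), PFKFB4 (-3.70) and TNFRSF10D (-3.66) with a lower one. Several of these rest on few counts, and their fitted values depend on the prior count. The MEIS1 call ended without KG1A PBS replicate 1 or 2, KG1A dG replicate 1 or 2, or U937 dG replicate 1 or 2 (adjusted p = 0.055 to 0.171), with no filter (0.0892), with DESeq2 (0.0971) and with each RPKM setting. The NRIP1 call ended with each RPKM setting, those of LPAR6 and COBLL1 with RPKM at a pseudocount of 0.1 (adjusted p = 0.475 and 0.0675), that of COBLL1 also with unfiltered RPKM (0.0884), and that of GBP2 with RPKM at a pseudocount of 1 (0.0884) and unfiltered RPKM (0.177). In U937, PBS against dG, NRIP1 had 0 and 9 counts, LPAR6 0 and 14, and COBLL1 0 and 6, while in KG1A GRB10 had 1 and 17 and MEIS1 0 and 4. MACC1 went from 8 to 214 counts in U937 (34.8-fold, 95% counting interval 17.3 to 81.6) and from 194 to 212 CPM in KG1A. GBP2 went from 8 to 216 counts in U937 (35.1-fold, 17.5 to 82.3) and from 50.9 to 82.0 CPM in KG1A. GATA3 went from 58 to 5 counts in U937 and from 1747 to 3377 in KG1A. TNFRSF10D went from 25 to 262 counts in KG1A (10.4-fold, 6.86 to 16.3) and from 39.7 to 32.2 CPM in U937.

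The 15 lists that differed by camera with the preset correlation, of which 7 passed with an estimated correlation, had these median differences of log2 fold change: glycolysis and hypoxia -1.09, MYC and ribosome biogenesis -0.82, DNA replication -0.61, purine synthesis and salvage -0.60, DNA damage checkpoint and repair -0.34, cytosolic ribosomal proteins -0.32, mitochondrially encoded mRNA -0.29 and G1/S cyclins and E2F -0.24. With a higher effect in U937 they were MHC class II presentation 2.75, replication-dependent histones 1.98, the unfolded protein response 1.13, cholesterol synthesis 0.78, interferon-stimulated genes 0.76, lysosome 0.65, and monocyte and macrophage markers 0.64. The 8 that did not pass were MHC class II presentation (adjusted p = 0.055 with an estimated correlation), DNA damage (0.0758), histones (0.0967), lysosome (0.119), G1/S (0.301), ribosomal proteins (0.319), monocyte markers (0.33) and mitochondrial mRNA (0.342). The monocyte, G1/S and mitochondrial mRNA calls ended without single libraries. The monocyte call ended without KG1A PBS replicate 1, KG1A dG replicate 1 or 2, U937 PBS replicate 1, or U937 dG replicate 1 or 2 (adjusted p = 0.0552 to 0.214). The G1/S call ended without KG1A dG replicate 1, U937 PBS replicate 1, or U937 dG replicate 1 or 2 (adjusted p = 0.0527 to 0.19), and the mitochondrial mRNA call without U937 dG replicate 2 (adjusted p = 0.0897).

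Genes of 1 line gained trace reads in the dG libraries of the other line: reads of 77 KG1A-specific genes numbered 142 and 110 in the U937 PBS libraries and 191 and 243 in the dG libraries (0.0208%, 0.0205%, 0.0363% and 0.0525% of their KG1A level), and reads of 51 U937-specific genes in KG1A numbered 51 and 85, then 138 and 100. A carryover of RNA or reads from the other line requires counts in proportion to levels in the source line, and the chi-square per gene against that proportion, with a bound of 2 set beforehand, was 3.445 for KG1A-specific genes in U937 dG in a first gene set picked by low PBS counts. In a second set, drawn over all 4 libraries, it was 2.0891 for KG1A-specific genes in U937 dG and 5.1663 for U937-specific genes in KG1A dG, and the 3 values became, in this order, 2.77, 1.86 and 3.21 without the gene that deviated most (in KG1A dG, CTSG, singled out after its counts were seen, held 64 of 238 reads). In the first set, U937-specific genes in KG1A dG gave 5.06, and 2.09 without the gene that deviated most. By the bound alone, each value with all genes counted against carryover in proportion. The 2 SD allowed around the bound were scaled to the observed value, so a larger misfit also widened them. With that allowance each comparison lay within 2 SD of the bound at least once, with all genes or without that gene. Carryover and expression were therefore not told apart in either line. The 5 named genes at trace level (NRIP1, LPAR6, COBLL1, GRB10 and MEIS1) had a median of 2.6605 times the reads that carryover would bring, but they had been picked for their excess in those libraries, which fixes that outcome, and with 4 to 17 reads each they leave it open as well.

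Replication-dependent histone genes rose in U937, with 14 higher and 1 lower among 20 measured genes of the histone clusters, while DNA replication genes fell. A wider share of cells in S phase was predicted to raise the replication list, but the median of that list was -0.49836. Levels of mRNA do not measure the share of cells in S phase, so a wider share stays open. Histone mRNAs of this class lack a poly(A) tail in cycling cells, and other RNAs without a tail rose with them in U937, at a median of 0.96899 over 40 RNAs, as carryover of such RNA through the mRNA selection requires. KG1A, where those 40 RNAs had a median of -0.31, had 4 higher and 0 lower of the same 20 histone genes. Polyadenylated histone transcripts, which appear in maturing cells, could also raise these counts, and this was not tested.

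Glycolysis and cholesterol synthesis moved apart between the lines. The smallest median difference of either list over 3 size factors was 0.76876 (log2 size), with the sign kept. Removing the trend of fold change on GC content and exon length left 95.216% or more of each difference, and without any 1 library the highest adjusted p of either list was 1.9349e-13. The values for GC content, exon length and left-out libraries argue against GC or length bias and a single library as the cause. For scaling the sign could hardly change, since DESeq2's size factors moved the median difference over all genes by only 0.10. A size factor shifts all genes alike, however, whereas the median differences were -1.09 for glycolysis and 0.78 for cholesterol synthesis. The hypothesis that the compound acted on sugar and sterol metabolism in opposite directions in the lines stays open, since the lines also differ in their PBS levels of these genes and in all else that sets them apart.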

How the results depend on the processing

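The restriction to genes expressed in the compared line was chosen after the data were seen. So were the common basis for the estimated correlation and fry, and the sign rule for lists that changed direction.

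Gene counts stayed within 1.5 times under every other normalization, filter, test and unit run, except at 2-fold, where fewer genes qualify by construction: 1244 in KG1A, 3195 in U937, 2026 for the difference and 8037 between the lines in PBS. DESeq2 gave 6541, 9322, 6021 and 13580. RPKM values with a pseudocount of 1 gave 7732, 10075, 8404 and 12441, with 4746 higher and 3658 lower for the difference. Genes expressed in the compared line numbered 8638 in KG1A, 10902 in U937 and 7408 for the difference. Without single libraries the counts ran from 7474 to 9028 in KG1A, 10492 to 11934 in U937, 7139 to 7763 for the difference, 14398 to 15457 in PBS, and 4434 to 4921 for genes called the same way in both lines. Lists ran from 19 to 22, 23 to 24 and 12 to 15. With an estimated correlation 1 list passed in KG1A, 4 in U937 and 7 for the difference, and with fry 29 for the difference, since fry tests each list without regard to other genes.

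Replicate numbers gave no sign of pairing. Across genes, deviations of log2 CPM from the group mean correlated at -0.05 (KG1A) and 0.01 (U937) between the PBS and dG libraries of the same number. With the number as a replicate block, 8742 genes passed in KG1A (8710 of them the same genes in the same direction), 11530 in U937 (11507) and 7835 for the difference (7800), 16 lists differed between the lines, with fibroblast markers added (adjusted p = 0.044), and the histone list in KG1A changed its test direction, at a median of 0.050.

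Of 325 results for named genes, 283 kept direction and side of the threshold under every one of the 20 settings in which they were tested, and 42 did not. Genes that the filter of a setting removed were not tested there. LPAR6 reversed for the difference at -0.56 with RPKM values (pseudocount 1, with or without a filter), where its 14 reads in U937 dG fall under the pseudocount. DCK in KG1A, not called, was -0.018 with library size only, -0.021 with no filter, -0.021 and -0.022 with RPKM (pseudocounts 1 and 0.1), -0.021 with unfiltered RPKM and -0.014 with the line fitted alone. Lists that changed test direction were not called by camera in that comparison. With fry in KG1A they were dNTP synthesis (median 0.060), MHC class II (-0.024), DNA replication (-0.011), erythroid markers (1.098) and fibroblast markers (-0.12). Of these, fry called dNTP synthesis (fry adjusted p = 0.0171) and DNA replication (fry adjusted p = 0.0158) upward, and did not call the others. Fry also called the dNTP list downward, as camera pointed without a call, in U937 (fry adjusted p = 0.0188) and for the difference (fry adjusted p = 0.00251). Fibroblast markers in KG1A gave -0.18 with library size only, and lymphoid markers 0.46 in U937 and -0.23 for the difference with DESeq2's size factors. For the difference, fry gave 0.11 for ATF4 genes and -0.33 for lymphoid markers. It pointed downward for both lists, with a call for ATF4 genes (fry adjusted p = 0.0426) and none for lymphoid markers (fry adjusted p = 0.144). The causes of these changes were not tested.

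Without single libraries, lists that were not called changed direction, with medians over these ranges: in KG1A DNA replication -0.077 to 0.015, histones -0.077 to 0.41 and fibroblast markers -0.19 to 0.43, and for the difference G2/M -0.13 to 0.030, ATF4 0.051 to 0.26 and lymphoid markers -0.076 to 0.65. DCK in KG1A ranged from -0.020 to 0.089, KIT in U937 from -1.50 to 0.20 and CD14 in U937 from -0.43 to 0.17. Depth limits genes such as CD14 and KIT in U937, with few counts per library.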

Other observations

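The 16 gene families below were defined after the data had been seen, several because their genes stood high in the tables, and their tests were chosen for that reason. Genes that are not subunits were removed from 3 families after their results had been seen.

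In KG1A, 10 of 10 platelet genes were higher, among them SELP (3.68 ± 0.15), ITGB3 (3.41 ± 0.12), ITGA2B (0.95 ± 0.03) and MMRN1 (0.91 ± 0.03). Of 11 mast cell and basophil genes 9 were higher and 0 lower, with CPA3 at 2.52 ± 0.04. Both families were drawn up because such genes stood among the largest rises, so their outcome was partly fixed by the choice and no value of a family test is given for them. In U937, 3 of the platelet genes were higher and 1 lower, and 5 of the mast cell and basophil genes were higher and 0 lower. MHC class I presentation rose in both lines (9 higher, 0 lower of 13 in KG1A, camera adjusted p = 2.51e-05, and 10 higher, 2 lower in U937, camera adjusted p = 4.48e-05). The values were adjusted p = 0.0864 and adjusted p = 0.159 with an estimated correlation.

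Mitochondrial ribosomal protein genes fell in both lines, 65 of 78 in KG1A with 0 higher and 63 in U937 with 6 higher (medians -0.39 and -0.66, camera adjusted p = 1.65e-20 and 1.01e-11, adjusted p = 0.0625 and adjusted p = 0.159 with an estimated correlation). Proteasome subunits fell as well, 32 of 37 in KG1A and 26 in U937 (medians -0.43 and -0.35, camera adjusted p = 2.83e-15 and 3.5e-06, adjusted p = 0.0864 and adjusted p = 0.202 with an estimated correlation). Chaperonin subunits fell in 8 of 9 genes in each line (medians -0.37 and -0.80, camera adjusted p = 8.91e-08 and 3.5e-06), with adjusted p = 0.0967 and adjusted p = 0.159 with an estimated correlation. V-ATPase subunits, which acidify lysosomes, rose in U937 (15 higher, 2 lower of 20, camera adjusted p = 2.22e-05, adjusted p = 0.159 with an estimated correlation) and were not called in KG1A (6 higher, 4 lower, camera adjusted p = 0.96). For the difference, 13 had a higher and 2 a lower U937 effect (camera adjusted p = 5.6e-07, adjusted p = 0.175 with an estimated correlation). No family passed with an estimated correlation in either line or for the difference, the platelet and the mast cell and basophil genes included. Leaving those 2 families aside, the lowest value was adjusted p = 0.0607 with an estimated correlation, for RNA polymerase I and III subunits in KG1A.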
